A study of Rattus norvegicus with 6 samples.

How the data were processed

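RNA of brain capillaries from stroke-prone spontaneously hypertensive rats (SHRSP) was measured on 6 Affymetrix RG_U34A arrays, 2 each for a control group, a group given the ACE inhibitor lisinopril (ACEI) and a group given the angiotensin receptor blocker olmesartan (ARB). The deposited table held 1 intensity per probe set and array for 8799 probe sets, on a linear scale with no value below 0 and no detection calls. The values showed that the deposited intensity of each array had been scaled to a mean, trimmed by 2% at either end, between 997.7 and 1002 per array. The software that made the values is not given in the sources used here, nor is its background correction or the origin of the scale. Per the file headers of the array runs, which hold text settings and other run details, control 1 and ACEI 1 were run on one day with one chip lot. Control 2, ACEI 2 and both ARB arrays were run on a later day with another lot. The fluidics protocol was one for control 1, ACEI 1 and ARB 1 and another for the remaining arrays. It therefore coincided with the replicate number, where the unnumbered control and ACEI titles were read as number 1.

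Probe sets were given genes from the array's annotation table: 7018 carried 1 gene symbol, 308 carried several and were named by none, and 1473 carried no symbol. Of the probe sets with 1 symbol, 6994 had a gene identifier in the reference gene table, no symbol needed an update (0 changed), and 4737 different genes were named. The 59 control probe sets were kept out of all gene tests, which left 8740. Genome positions were not used here.

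Intensities were transformed as log2 of the value plus an offset of 90, the median of all values above 0 (358.3) divided by 4 and rounded. Because the trimmed means of the arrays lay close together, no further normalization between arrays was applied. The 40% of probe sets with the lowest mean were left out, and 5244 were tested. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with moderated statistics (3 residual and 5.49 prior degrees of freedom), two-sided p-values and Benjamini-Hochberg adjustment at 0.05. The contrasts were RAS blockade (the mean of ACEI and ARB) versus control, ACEI versus control, ARB versus control and ARB versus ACEI. Values below are log2 differences ± SE of the model. Tables and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

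The 21 gene lists, the filter, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The lists covered the angiotensin system, brain endothelium, blood-brain barrier transporters and junctions, pericytes and smooth muscle, astrocytes, neurons, oligodendrocytes, microglia and macrophages, erythroid and blood cells, choroid plexus and ependyma, oxidative stress, inflammation and leukocyte adhesion, extracellular matrix, vasoactive signalling, immediate early genes, heat shock, angiogenic factors, the cell cycle, oxidative phosphorylation, glycolysis and ribosomal proteins. Each list was tested by camera in limma at the level of 3186 genes (1 probe set per gene, the one with the highest mean) with a preset correlation between genes of 0.01, adjusted over the lists and the 3 contrasts against control, and separately over the lists for ARB versus ACEI. Camera with an estimated correlation, fry and the mean of all probe sets of a gene were alternatives. Named genes were, per contrast against control, up to 10 higher and 10 lower genes by size of the log2 difference, and 5 in each direction for ARB versus ACEI. Genes past an adjusted p of 0.05 came first, and places were filled with genes at an unadjusted p under 0.01 whose treated arrays all lay beyond both control arrays. A fixed set that included the angiotensin system genes Agt, Ace and Agtr1a, endothelial genes and Icam1, Ccl2, Acta2 and Hmox1 was always given, as were up to 4 members of each list with the largest absolute difference.

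The alternatives were no offset, an offset equal to the median, no filter, a filter of 60%, quantile and cyclic loess normalization, the replicate number as a block, the run day as a block, array weights, another variance prior, an ordinary test without moderation, a fit of only the groups compared, and leaving out each array in turn. A fit of the 4 arrays of the later run day alone was added after the data had been seen. A rank product was computed as a description.

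The test was also run on simulated data of 5244 probe sets and 2 arrays per group with 200 changed probe sets and 10 simulations. For RAS blockade it recovered 4.48% of 2-fold, 63.4% of 4-fold and 97.3% of 8-fold changes; for ACEI these were 1.64%, 37.5% and 91.5%, for ARB 2.39%, 39.9% and 90.5%, and for ARB versus ACEI 1.79%, 33.6% and 86.2%. Between 6.15% and 6.93% of the simulated calls were false. For each probe set the simulated spread was the same on all arrays. In the data 34.5% of probe sets differed over 2-fold within the control pair, against 17.8% (ACEI) and 15.2% (ARB). The adjustment also depends on how many probe sets change. The recovery rates may therefore not hold for the data, where Spp1 at 13.3-fold lower with RAS blockade was not called. A list of 32 genes shifted by -0.5 was recovered in 100% of simulations with the preset correlation and in 0% with an estimated one, and 0.556% of unshifted lists were called. The simulated genes varied independently of each other. These rates therefore do not cover lists whose genes move together, as the endothelial markers did between the control arrays (mean -1.39 on control 2 minus control 1). A missing call with an estimated correlation does not speak against a shift of that size. For arrays the number of arrays limits the precision, and groups of 2 cannot give a small exact permutation p. Whether the 2 arrays of a group came from separate animals or pools is not given in the sources used here, so the p-values measure a spread between samples that may be technical.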

Results

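Brain capillaries of 6-week-old SHRSP, a rat strain with inherited high blood pressure and strokes, were profiled on 6 arrays in 3 groups of 2. Lisinopril lowers the formation of angiotensin II and was given at 6 mg/kg per day, and olmesartan blocks the angiotensin type 1 receptor and was given at 4 mg/kg per day. The labels also name 1% NaCl, and whether all groups or only the controls received it is not given in the sources used here. The median intensity was 317.7 and 257.9 on control 1 and control 2, 353.4 and 244.9 on the ACEI arrays, and 485.7 and 493.8 on the ARB arrays.

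The arrays of a group were not equally alike. Across probe sets, which are not independent replicates, the log2 values of the control pair had a Pearson correlation of 0.747 and 34.5% of probe sets differed by more than 2-fold, against 17.8% within the ACEI pair and 15.2% within the ARB pair. The ratio of the 3' to the 5' probe set of Gapdh, a glycolytic enzyme whose ratio is raised where RNA is degraded or incompletely copied, was 7.31 on control 2 and between 0.93 and 1.59 on the other 5 arrays. The signal of the added bioB, bioC, bioD and cre controls had a median of 7525 and 5387 on the ARB arrays and between 1012 and 3274 on the other 4 arrays. The 10 brightest probe sets held 11.3% and 12.2% of the signal on the ARB arrays and between 2.56% and 5.64% on the others.

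**Figure D1:**
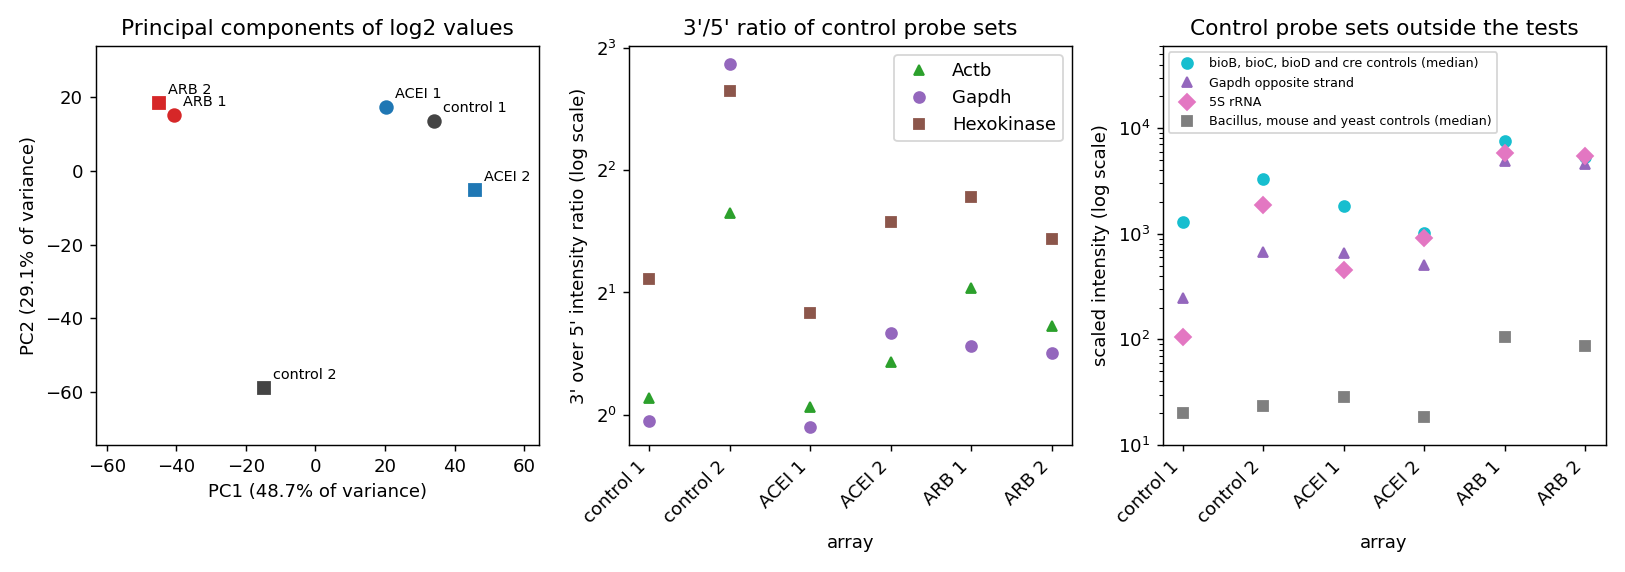
The 6 arrays on the principal components of their log2 values (left, 48.7% and 29.1% of the variance), the ratio of 3' to 5' probe sets of Actb, Gapdh and hexokinase (middle, log axis) and the scaled intensity of control probe sets outside the tests (right, log axis), 1 point per array and measure. Control 2 lies apart and has the highest ratios (7.31 for Gapdh), and the ARB arrays have the highest added controls (7525 and 5387).

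RAS blockade versus control tested the mean of both drugs, which lower the formation of angiotensin II or block its receptor, so a call here need not hold for each drug. Spp1, which encodes the matrix protein and cytokine osteopontin, had an intensity of 3875 and 4673 on the control arrays and of 115 to 317 on the 4 treated arrays, a difference of -3.73 ± 0.42 (13.3-fold lower, n = 2 control and 4 treated arrays). Alox15, a lipoxygenase of eicosanoid synthesis found in macrophages and eosinophils, differed by -3.70 ± 0.46 (13.0-fold lower), and its other probe set by -4.66. Next among the lower genes, at 1 probe set per gene, were Lgals3 (galectin-3 of macrophages) -2.21 ± 0.38, S100a8 and S100a9 (the subunits of calprotectin of neutrophils and monocytes) -2.17 ± 0.51 and -2.11 ± 0.50, and Alas2 (haem synthesis in erythroid cells) -2.12 ± 0.52. All of these were lower on each of the 4 treated arrays than on both controls, which the rule for filled places required of them. None passed the adjustment over all 5244 probe sets in limma, where Spp1 had an adjusted p of 0.0779 and Alox15 of 0.0828. Over the alternatives the difference of Spp1 lay between -2.94 and -4.20.

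The list of inflammation and leukocyte adhesion genes fell with RAS blockade. Of its 32 measured members 23 were lower, with a mean difference of -0.59, or -0.68 relative to the genes outside the list (adjusted p = 1.52e-06, and adjusted p = 0.464 with an estimated correlation). In limma 0 members passed over all genes, 10 were lower at an unadjusted p under 0.05, and 6, all lower, passed when adjusted over the list alone. Examples were Ccl2, a chemokine that attracts monocytes, at -2.06 ± 0.74, the cytokine Il1b at -1.98 ± 0.52, Nfkbia, the inhibitor of NF-kappa-B that NF-kappa-B itself induces, at -1.57 ± 0.47, and the neutrophil chemokine Cxcl2 at -1.53 ± 0.39. Icam1, the endothelial ligand that lets leukocytes adhere, had an intensity of 5542 and 5525 on the control arrays and of 1706 to 2743 on the treated arrays, a difference of -1.37 ± 0.40. The other probe sets of these genes had smaller or larger differences of the same sign: -0.63 for Ccl2, -0.93 and -2.38 for Il1b, -0.21 for Nfkbia and -0.76 for Icam1. Ccl2 was at -3.16 without control 1 and -0.97 without control 2, and Il1b at -1.30 without control 2. Vcam1, another adhesion receptor, was at 0.36 ± 0.40, and its other probe set at -0.43. With the run day as a block the list mean was -0.62. ACEI minus control was -0.69 within the first run day and -0.29 within the later one, where ARB minus control was -0.64.

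The lists of immune and blood cells fell as well. Of 17 microglia and macrophage markers 12 were lower (mean -0.38, relative -0.46, adjusted p = 0.00552, and adjusted p = 0.466 with an estimated correlation), and 1 passed when adjusted over the list alone. By its mean the fall was larger with ARB (-0.63), and with ACEI the list was not called (mean -0.12, median 0.05, 9 of 17 higher, adjusted p = 0.424). Besides Lgals3 these included C1qb, a complement subunit made by microglia, at -1.30 ± 0.51 (other probe set -0.53) and the lysozyme gene Lyz2 at -1.06 ± 0.41. RT1-Da, a class II antigen-presenting molecule, was at -1.08 ± 0.40, while its other probe set was at 0.19. Cd74 and Aif1 of the same cells, chosen after their values were seen like the globin gene Hbb, were at -0.06 ± 0.54 and -0.08 ± 0.43. Within run days the list mean for ACEI minus control was -0.74 and then 0.49, and the call was lost without control 1 (mean -0.01) and without ACEI 1 (-0.25), while without control 2 the mean was -0.74. With the lowest 60% left out the call was lost too. Of 11 erythroid and blood cell markers 8 were lower (mean -0.73, relative -0.81, adjusted p = 0.00136, and adjusted p = 0.464 with an estimated correlation), and 3 passed when adjusted over the list alone. S100a8, S100a9, Alas2 and the globin gene Hbb-b1 (-1.29 ± 0.62) had the largest differences, while Hbb was at -0.17 ± 0.57. Hbb-b1 was at -2.25 without control 1 and -0.33 without control 2. The blood cell mean for ACEI minus control was -0.60 within the first run day and -0.87 within the later one, and for ARB minus control -0.92. For RAS blockade it was -0.54 without control 2, where the call was lost. With no filter the RAS blockade mean was -0.34 and with the lowest 60% left out -1.28, and the call held in both.

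Genes of the vessel wall and its matrix fell as lists. Of 33 extracellular matrix genes 23 were lower (mean -0.36, relative -0.44, adjusted p = 0.00216, and adjusted p = 0.464 with an estimated correlation), with 7 lower at an unadjusted p under 0.05 and 1 past the adjustment over the list alone. After Spp1 the largest members were the proteoglycan decorin, Dcn, at -1.93 ± 0.63 (other probe sets -0.53 and 0.40), the metalloproteinase inhibitor Timp1 at -1.72 ± 0.68 (-2.66; -2.59 and -0.85 without control 1 and control 2), and the growth factor Tgfb1 at 1.57 ± 0.81, where control 2 alone was low at 78.4 and the difference without it was -0.09. Of 16 pericyte and smooth muscle markers 12 were lower (mean -0.28, relative -0.36, adjusted p = 0.0381, and adjusted p = 0.464 with an estimated correlation), and 0 passed when adjusted over the list alone in limma, with 2 at an unadjusted p under 0.05. Acta2, smooth muscle actin, had an intensity of 19511 and 23120 on the controls and of 7200 to 9605 on the treated arrays, a difference of -1.31 ± 0.39, but its other 2 probe sets were at 0.05 and 0.03. The contractile genes Actg2 and Tagln were at -1.15 ± 0.58 (-0.67 without ARB 1) and -1.04 ± 0.41 (-0.66 without control 2), and Anpep, an aminopeptidase of pericytes that degrades angiotensin peptides, at 0.91 ± 0.50 (other probe set -1.08, and 0.41 without control 1). With the run day as a block the matrix mean was -0.30 and the pericyte mean -0.26, where the pericyte call was lost. Within run days ACEI minus control was -0.37 and -0.61 for matrix and -0.29 and -0.46 for pericytes. With ARB neither list was called: matrix had a mean of -0.22 (median -0.06, 17 of 33 lower, adjusted p = 0.106) and pericytes of -0.19 (10 of 16 lower, adjusted p = 0.179), and within the later run day -0.17 and -0.18. The pericyte call was also lost under quantile (mean -0.31) and cyclic loess normalization (mean -0.30), and without any single array but ARB 2 (-0.23 to -0.33), as it was with no offset, with the lowest 60% left out and over the mean of all probe sets of a gene (-0.15). The matrix call was lost without control 1 (mean -0.30, adjusted p = 0.206), and the matrix mean over all probe sets was -0.24.

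Neuronal markers rose. Of 33 measured members 30 were higher (mean 0.61, relative 0.53, adjusted p = 2.22e-05, and adjusted p = 0.464 with an estimated correlation), with 8 higher at an unadjusted p under 0.05 and 0 past the adjustment over the list alone in limma. The synaptic vesicle GTPase Rab3a was at 1.95 ± 0.48, the neuronal ubiquitin hydrolase Uchl1 at 1.51 ± 0.42 (other probe set 1.21), the GABA receptor subunit Gabrb2 at 1.42 ± 0.58 and the neurofilament gene Ina at 1.19 ± 0.55. Rab3a had an intensity of 114 and 13.3 on the controls and of 326 to 824 on the treated arrays. As 13.3 lies below the median of 23.3 of the control probe sets for foreign transcripts on that array, the size of its difference depended on the offset (1.00 to 3.59 over the alternatives). Without control 1 Gabrb2 was at 0.41 and Ina at 0.32, and without control 2 at 2.43 and 2.06. The list mean for ACEI minus control was 0.64 within the first run day and 0.20 within the later one, where ARB minus control was 0.65, and it was 0.59 with the run day as a block. Without control 1 it was 0.47 and the call was lost (adjusted p = 0.0549), and after quantile normalization it was 0.40. Other higher genes by the rule were the plakophilin gene Pkp4 1.77, the leptin receptor Lepr 1.77 (1.17 without control 1), the serine dehydratase Sds 1.76, the kainate receptor subunit Grik5 1.67 and the kinase genes Pnck 1.65 and Dapk3 1.58 (other probe set 2.80). Cabp1, a neuronal calcium-binding protein, was at 1.57 and Rassf9 at 1.52. Over the alternatives Pkp4 ran from 1.11 to 2.32, Lepr from 1.03 to 2.43 and Sds from 1.04 to 2.42. Pnck ran from 1.02 to 2.14 and Rassf9 from 0.77 to 2.48. The remaining lower genes were Ybx3, a cold shock domain protein, -2.01, the calcium-binding protein S100a4 -1.86 and the sulfotransferase Sult1a1 -1.68 (other probe set -2.14).

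Ribosomal and mitochondrial genes also fell, by amounts that depended on the scaling. Of 36 ribosomal protein genes 32 were lower (mean -0.46, relative -0.54, adjusted p = 8.62e-06, and adjusted p = 0.506 with an estimated correlation), among them Rpl22 -1.25, Rpl35a -1.10, Rps6 -1.02 and Rpsa -1.01. Without control 2 these were at -0.70, -0.28, -0.30 and -0.54, and the other probe sets of Rps6 and Rpsa were at -0.31 and -0.34. Of 34 oxidative phosphorylation genes 25 were lower (mean -0.22, relative -0.31, adjusted p = 0.0177, and adjusted p = 0.748 with an estimated correlation), and with ACEI alone the list was not called (mean -0.18, adjusted p = 0.330). Examples were the cytochrome oxidase subunit Cox6b1 -0.78 and the ATP synthase subunit Atp5po -0.77. Without control 2 these were at -0.19 and 0.54, and their other probe sets were at -0.19 and 0.05. The median difference of all probe sets was 0.13 and became -0.03 after quantile and 0.02 after cyclic loess normalization. Relative to the other genes the ribosomal mean was then -0.18 and -0.19, and the oxidative phosphorylation mean -0.04 and -0.06. The oxidative phosphorylation mean was 0.30 for ACEI minus control within the first run day and -0.66 within the later one, -0.68 without control 1, 0.23 without control 2 (call lost), and higher by 0.92 on control 2 than on control 1. The ribosomal mean was -0.22 and -0.41 within the run days, -0.80 without control 1, -0.11 without control 2 (call lost, adjusted p = 0.0951), and higher by 0.69 on control 2 than on control 1. Both calls were also lost after quantile and cyclic loess normalization, and the oxidative phosphorylation call with the lowest 60% left out. Over the mean of all probe sets of a gene its mean was -0.15.

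The angiotensin system genes and the endothelial markers did not pass as lists. Of 10 angiotensin system genes 8 were higher (mean 0.30, adjusted p = 0.370): the precursor Agt was at 0.24 ± 0.42, the converting enzyme Ace at 0.49 ± 0.73, the peptidases Lnpep and Cma1 at 0.77 and 0.70, and the glucocorticoid receptor Nr3c1 at -0.56. The receptor gene Agtr1a was at 0.21 ± 0.49, and at -0.11 and -0.10 after quantile and cyclic loess normalization. Ace had an intensity of 9110 on control 1 and 1346 on control 2, so its difference was -0.85 without control 2. Agtr1b lay below the filter, and Cldn5 and Gfap had no named probe set in the annotation used. Of 18 endothelial markers 13 were higher (mean 0.25, adjusted p = 0.583), including the transferrin receptor Tfrc 1.11 and the efflux pump Abcb1a 0.92, with the adhesion molecule Icam2 at -0.92 and the transporter Slco1a5 at 0.87. Without control 2 Tfrc was at -0.53, Abcb1a at -0.24 and Slco1a5 at 0.04, and without control 1 at 2.76, 2.08 and 1.69. Several were far lower on control 2 than on control 1: the junction molecule Pecam1 at 194 against 5538, the vasoconstrictor gene Edn1 at 234 against 3014, the nitric oxide synthase Nos3 at 262 against 2068, and the clotting factor Vwf at 49.2 against 596. Their differences were 0.18 ± 1.01 for Pecam1 (-0.19 after quantile normalization), 0.49 ± 0.82 for Edn1, 0.34 ± 0.67 for Nos3 and 0.43 ± 0.63 for Vwf, and all 4 were below 0 without control 2. The other probe set of Vwf was at -0.43, and the other 4 of Nos3 at -0.32, -0.22, 0.11 and 0.24. Slc2a1, the glucose transporter of the barrier, was at -0.51 ± 0.44 (other probe set -0.71, and -0.02 without control 2), and the haem oxygenase Hmox1 at -0.81 ± 0.42 (other probe set -0.37, and -0.51 without control 1).

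In all, limma called 0 of 5244 probe sets for RAS blockade, while 266 had an unadjusted p under 0.05 (160 higher and 106 lower), and 8 of 21 lists were called, 1 up and 7 down. The 4 treated arrays lay entirely beyond the controls for 8.35% of probe sets, where chance gives 13.3%. With the replicate number as a block 3 probe sets passed (Alox15 at -4.66 and -3.70, Spp1 at -3.73), and with the run day as a block 0 passed, with a lowest adjusted p of 0.328. Without control 1 or control 2 the control group is a lone array, so the calls of those fits are not counted.

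**Figure D2:**
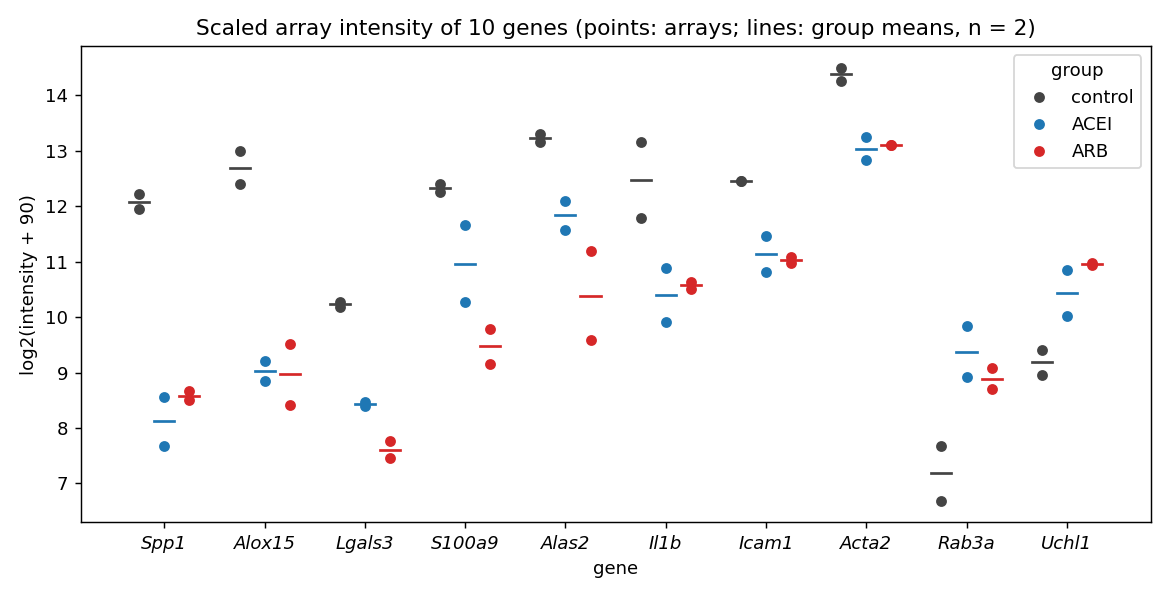
Log2 of intensity plus 90 for 10 named genes, with 1 point per array coloured by group and a line at each group mean (n = 2). For Spp1, Alox15, Lgals3, S100a9, Alas2, Il1b, Icam1 and Acta2 all 4 treated arrays lie below both controls, and for Rab3a and Uchl1 above them. The rule for filled places required this of all but Icam1 and Acta2, which were in the fixed set.

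**Figure D3:**
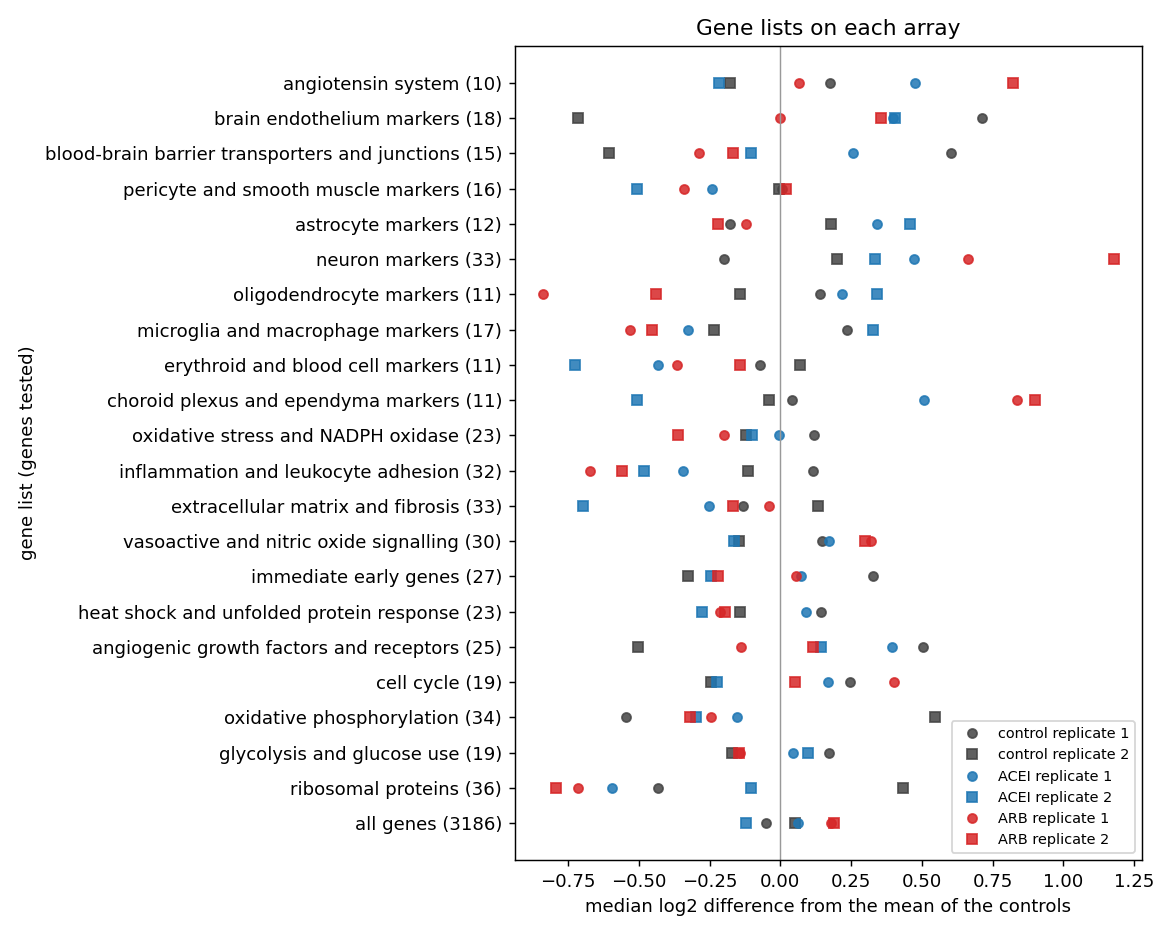
Median over the genes of each list of the log2 difference from the mean of the 2 control arrays, with 1 point per array, colours for groups, shapes for replicates and the number of genes tested in brackets. The inflammation list lies at -0.34 and -0.48 on the ACEI arrays and at -0.67 and -0.56 on the ARB arrays, and the endothelial list at 0.71 and -0.71 on control 1 and control 2.

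ACEI versus control asked what lisinopril did to capillary genes. Spp1 was 15.6-fold lower (-3.97 ± 0.49, 2 arrays per group) and Alox15 12.8-fold lower (-3.67 ± 0.54), with adjusted p of 0.148 and 0.259 in limma. The cytokine genes Il1b and Il1a were at -2.07 ± 0.60 (other probe sets -0.75 and -1.75) and -1.76 ± 0.46 (-2.19), and Lgals3 at -1.79 ± 0.44. Errfi1, a feedback inhibitor of the EGF receptor, was at -1.91 ± 0.54 (other probe set -0.71) and Padi4, the neutrophil enzyme that citrullinates histones, at -1.90 ± 0.48. Higher by the rule were the tyrosine kinase Matk 3.14 ± 0.58, Pkp4 2.69 ± 0.58, Rab3a 2.19 ± 0.55, the acetyltransferase Kat5 1.78 ± 0.45 and Pnck 1.77 ± 0.51. Over the alternatives Kat5 ran from 1.02 to 2.47 and Padi4 from -2.60 to -1.12. Matk and Rab3a had intensities of 26.3 and 13.3 on control 2, just above and below the level of control probe sets for foreign transcripts (23.3), so their sizes depended on the offset (2.03 to 4.41 and 1.17 to 3.87 over the alternatives). Within the first and the later run day the values were -3.40 and -4.54 for Spp1, -3.20 and -4.15 for Alox15, 2.16 and 2.22 for Rab3a, and 2.70 and 2.67 for Pkp4.

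With ACEI 8 of 21 lists were called, 3 up and 5 down. The inflammation list fell, with 22 of 32 members lower (mean -0.49, adjusted p = 0.000339, and adjusted p = 0.464 with an estimated correlation), and Icam1 was at -1.32 ± 0.46 (other probe set -0.61). Extracellular matrix genes fell, with 26 of 33 lower (mean -0.49, adjusted p = 0.000400, and adjusted p = 0.464 with an estimated correlation), Timp1 being at -1.89 ± 0.79. The blood cell list fell (mean -0.73, 9 of 11 lower, adjusted p = 0.000735), as did pericyte and smooth muscle markers (mean -0.37, 11 of 16 lower, adjusted p = 0.0482), and both had an adjusted p = 0.464 with an estimated correlation. Neuronal markers rose (mean 0.42, 23 of 33 higher, adjusted p = 0.000339), as did astrocyte markers (mean 0.34, 9 of 12 higher, adjusted p = 0.0324), and both had an adjusted p = 0.466 with an estimated correlation. Endothelial markers rose (mean 0.62, 13 of 18 higher, adjusted p = 0.00636, and adjusted p = 0.466 with an estimated correlation), with Pecam1 at 1.66 ± 1.17, Edn1 at 1.15 ± 0.95 and Nos3 at 0.99 ± 0.78, which without control 2 were at -0.50, -0.48 and -0.31. The endothelial difference was -0.08 within the first run day and 1.31 within the later one, so the list was below 0 without control 2 and at 1.31 without control 1. The call was also lost without ACEI 2 (0.61). Ribosomal genes fell (mean -0.31, 28 of 36 lower, adjusted p = 0.0283, and adjusted p = 0.752 with an estimated correlation), with a mean of 0.03 without control 2 and -0.06 without ACEI 1 (call lost), and of -0.66 without control 1 and -0.56 without ACEI 2. Without control 1 the calls of the inflammation (mean -0.44), matrix (-0.44), pericyte (-0.36), neuronal (0.28) and astrocyte lists (0.17) were lost as well. After quantile and cyclic loess normalization the ribosomal and pericyte calls were lost, and with no offset as well. Over the mean of all probe sets of a gene the pericyte fall disappeared (mean -0.03, adjusted p = 0.945) and the astrocyte mean was 0.53. The inflammation call was lost without ACEI 1 too (-0.35, adjusted p = 0.251), the astrocyte call without ACEI 2 (0.22) or ARB 1 (0.34), and the pericyte call without ACEI 1 (-0.47) or ACEI 2 (-0.28). The pericyte call was also lost with the lowest 60% left out and with the run day as a block (mean -0.37, adjusted p = 0.0687), and with the replicate block the pericyte and astrocyte calls were lost. Blood cell markers had a mean of -0.39 with no filter, neuronal markers of 0.27 with an offset equal to the median, and without ACEI 2 the matrix mean was -0.31. The angiotensin genes gave 0.87 ± 0.48 for Agt, 0.46 ± 0.84 for Ace and -0.65 ± 0.57 for Agtr1a. Leaving out 1 array turned Ace to -0.88 (control 2) and Agtr1a to 0.08 (ACEI 2).

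Limma called 0 probe sets for ACEI, with 136 at an unadjusted p under 0.05 (63 higher and 73 lower), and the pairs of arrays were separated for 23.5% of probe sets where chance gives 33.3%. The replicate block gave 2 calls (Alox15 at -4.57 and Spp1 at -3.97, both at an adjusted p of 0.0404). The run day block gave 0 with a lowest adjusted p of 0.472. Without control 1 the control group is control 2 alone, so the calls of that fit are not counted.

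ARB versus control asked the same of olmesartan, whose arrays carried the raised control signals described above. Alox15 was 13.3-fold lower (-3.73 ± 0.54, 2 arrays per group) and Spp1 11.3-fold lower (-3.50 ± 0.49), each with an adjusted p of 0.154 in limma. S100a8 was at -3.27 ± 0.59, S100a9 at -2.86 ± 0.57, Alas2 at -2.84 ± 0.60 and Lgals3 at -2.62 ± 0.44, and Icam1 and Ccl2 were at -1.42 ± 0.46 and -2.62 ± 0.85 (other probe sets -0.92 and -0.58), Ccl2 being at -1.52 without control 2 and -1.68 without ARB 2. Other lower genes were Oaz1, the inhibitor of polyamine synthesis, -2.92 ± 0.54, the growth factor receptor Igf1r -2.91 ± 0.61 (other probe set 0.51), Dcn -2.56 ± 0.73 (other probe sets -0.29 and 0.62, and -1.54 without ARB 1) and the lipid droplet protein Plin2 -2.54 ± 0.53. Higher by the rule were the liver cytochrome Cyp2c11 3.43 ± 0.53, the bile acid enzyme Akr1d1 3.27 ± 0.57, Prrc2c 2.91 ± 0.86, the olfactory receptor Or1ad6 2.68 ± 0.69, Dapk3 2.57 ± 0.47 (other probe set 3.64), the glutamate receptor subunit Grin3a 2.48 ± 0.56, Cabp1 2.48 ± 0.45, the glycine transporter Slc6a5 2.46 ± 0.58, the potassium channel Kcnh1 2.46 ± 0.67 (1.45 without control 1) and the nuclease Dnase1 2.41 ± 0.44. Kcnh1 had an intensity of 13.4 on control 1, below the level of the control probe sets for foreign transcripts (19.9), and its size depended on the offset (1.49 with an offset equal to the median and 3.99 with none). Over the alternatives Or1ad6 ran from 1.70 to 3.83 and Slc6a5 from 1.55 to 3.25. On an ARB array Lgals3 (84.9), S100a8 (79.6), Ccl2 (88.8) and Dcn (108.5) were near the level of those control probe sets (105.6 and 86.6), which limits the size of their falls. Within the later run day Spp1 was at -3.63, Alox15 at -4.03, S100a8 at -3.27 and Cyp2c11 at 3.25. No ARB array was run on the first day, so these are the differences from control 2 alone.

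With ARB 7 of 21 lists were called, 1 up and 6 down. The inflammation list fell, with 25 of 32 members lower (mean -0.70, relative -0.88, adjusted p = 4.45e-05, and adjusted p = 0.464 with an estimated correlation), and 2 passed when adjusted over the list alone. Microglia and macrophage markers fell (mean -0.63, 12 of 17 lower, adjusted p = 0.00296, and adjusted p = 0.466 with an estimated correlation), with 4 past the adjustment over the list alone and C1qb at -2.12 ± 0.59. The blood cell list fell by its mean of -0.73, while its median was -0.03 and 6 of 11 members were lower (adjusted p = 0.0482, and adjusted p = 0.464 with an estimated correlation). Oligodendrocyte markers fell (mean -0.61, relative -0.78, 9 of 11 lower, adjusted p = 0.0191, and adjusted p = 0.464 with an estimated correlation), with the myelin enzyme Cnp at -2.02 ± 0.65. Neuronal markers rose (mean 0.79, relative 0.62, 30 of 33 higher, adjusted p = 0.000932, and adjusted p = 0.466 with an estimated correlation), with means of 0.44 after quantile and 0.47 after cyclic loess normalization. Ribosomal genes fell (mean -0.60, 31 of 36 lower, adjusted p = 1.53e-05, and adjusted p = 0.517 with an estimated correlation), as did oxidative phosphorylation genes (mean -0.27, 24 of 34 lower, adjusted p = 0.0207, and adjusted p = 0.750 with an estimated correlation). The median difference of all probe sets was 0.18, and -0.07 after quantile and -0.00 after cyclic loess normalization. Relative to the other genes the ribosomal mean was then -0.23 and -0.22, and the oxidative phosphorylation mean was -0.01 after either one, where both calls were lost. Before them the oxidative phosphorylation mean was 0.19 without control 2 (call lost) and -0.73 without control 1, and the ribosomal mean was -0.26 and -0.94. Without control 1 the microglia mean was -0.27 (adjusted p = 0.260) and the oligodendrocyte mean -0.42 (adjusted p = 0.213), and both calls were lost. Without control 2 the microglia mean was -0.99. With the run day as a block the oligodendrocyte (mean -0.52, adjusted p = 0.0711) and blood cell calls (-0.85, adjusted p = 0.0605) were lost, the oligodendrocyte call also after cyclic loess normalization (mean -0.60). The blood cell call was also lost without control 1 (-0.92), control 2 (-0.54, adjusted p = 0.313), ACEI 1 or ACEI 2 (both -0.73), with no offset and with no filter (-0.30), while with the lowest 60% left out its mean was -1.52. With the lowest 60% left out the microglia, oligodendrocyte and oxidative phosphorylation calls were lost. Within the later run day the means were -0.64 for inflammation, -0.27 for microglia, -0.42 for oligodendrocytes, 0.65 for neurons, -0.94 for ribosomal and -0.73 for oxidative phosphorylation genes. Both ARB arrays are of that day, so these are the differences from control 2 alone. They equal the means without control 1 and are not a separate check. Agt was at -0.40 ± 0.48 (-0.08 without control 1 and -0.72 without control 2), Ace at 0.52 ± 0.84 (1.86 and -0.82) and Agtr1a at 1.06 ± 0.57.

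Limma called 0 probe sets for ARB, with 905 at an unadjusted p under 0.05 (659 higher and 246 lower), and the pairs were separated for 50.1% of probe sets where chance gives 33.3%. The replicate block gave 4 calls (both probe sets of Alox15, Spp1 and an unnamed probe set at 3.51). The run day block gave 0 with a lowest adjusted p of 0.168. Fits without control 1 or control 2 rest on a lone control array, so their calls are not counted.

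ARB versus ACEI tested directly whether the drugs differ. Higher with ARB by the rule were Akr1d1 by 3.80 ± 0.57 (14.0-fold, 2 arrays per group), Prrc2c by 3.71 ± 0.86, Cyp2c11 by 3.70 ± 0.53, a probe set annotated as the acute phase protein gene Crp by 3.54 ± 0.99 (other probe set 3.65) and the olfactory receptor Or8g20b 8.01-fold (SE 0.70 in log2). The Crp probe set had 1531.5 and 5940 on the controls, 5506 and 539 with ACEI, and 22437 and 20892 with ARB. The Prrc2c probe set followed it closely (1504.5 and 5038, 3910.5 and 588.5, 23087 and 19941.5). Which gene either probe set measures is therefore uncertain, here and against control. Without ACEI 2 Prrc2c was at 2.43, Crp at 1.96 and Or8g20b at 1.88. Cyp2c11 had an intensity of 15.8 on ACEI 2, below the level of the foreign controls (18.4), and its size depended on the offset (2.39 with an offset equal to the median). Lower with ARB were Lgals9 (galectin-9) at -4.17 ± 1.09 (other probe set -0.41), the glycolytic enzyme Aldoa at -4.12 ± 1.14, the collagen chaperone Serpinh1 at -3.48 ± 0.82, the spectrin Sptan1 at -3.15 ± 0.79 and the NADPH oxidase subunit Cyba at -2.99 ± 0.59. Lgals9, Aldoa, Serpinh1 and Sptan1 were low on control 2 too: Lgals9 had intensities of 745 and 317 with ARB and of 576 on control 2, against 10575 on control 1 and 9741 and 11187 with ACEI. Spp1 and Alox15 differed between the drugs by 0.47 ± 0.49 and -0.06 ± 0.54, and the sign for Spp1 turned to -0.19 after quantile normalization.

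Between the drugs 5 lists were called, all lower with ARB. Oligodendrocyte markers had a mean of -1.03 (10 of 11 lower, adjusted p = 0.00274), endothelial markers of -0.73 (13 of 18 lower, adjusted p = 0.0271), microglia and macrophage markers of -0.51 (13 of 17 lower, adjusted p = 0.0271) and astrocyte markers of -0.49 (7 of 12 lower, adjusted p = 0.0398), each with an adjusted p = 0.489 with an estimated correlation. Ribosomal genes had a mean of -0.29 (26 of 36 lower, adjusted p = 0.0190, and adjusted p = 0.775 with an estimated correlation). After quantile normalization the ribosomal (mean -0.13, adjusted p = 0.563) and astrocyte calls (-0.57) were lost. After cyclic loess the ribosomal (-0.09, adjusted p = 0.680), astrocyte (-0.37), endothelial (-0.88) and microglia calls (-0.63) were lost, and the oligodendrocyte call held (-1.01, adjusted p = 0.0238). When adjusted over the list alone 3 oligodendrocyte, 2 astrocyte and 1 endothelial gene passed. Mbp, the myelin basic protein, was at -3.51 ± 1.09, with 626 and 669 on the ARB arrays, 234 on control 2, 5492 on control 1 and 9125 and 7593 with ACEI. The endothelial genes Pecam1 and Cav1 were at -2.97 and -3.12, and the astrocyte genes Aldoc and Glul at -2.84 and -1.86 (other probe sets of Glul -1.21 to -2.59). Aldoc, Cav1 and the further members Qdpr -1.48 and Mog -1.25 of the oligodendrocyte list were chosen after their values were seen. Within the later run day the means were -1.05, -0.74, -0.76, -0.61 and -0.54 for the oligodendrocyte, endothelial, microglia, astrocyte and ribosomal lists. With the run day as a block they were -0.94, -0.39, -0.46, -0.63 and -0.58. The endothelial call was lost, and oxidative phosphorylation was called instead (-0.31, adjusted p = 0.0122). Without ARB 1 only the oligodendrocyte call held, at endothelial, microglia, astrocyte and ribosomal means of -0.75, -0.47, -0.53 and -0.32. The endothelial call was lost without ACEI 1 (-0.74), the microglia and ribosomal calls without ACEI 2 (-0.26 and -0.04), and the astrocyte call without ACEI 2 (-0.37), ARB 2 (-0.45) or either control (-0.49). The ribosomal mean without ACEI 1 was -0.54.

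Limma called 0 probe sets between the drugs, with 1171 at an unadjusted p under 0.05 (819 higher and 352 lower), a lowest adjusted p of 0.110, and separated pairs for 62.4% of probe sets where chance gives 33.3%. A fit of these 4 arrays alone, or without either control, gave 305 calls (148 higher and 157 lower), array weights gave 476, the replicate block 1 (an unnamed probe set at 3.97) and the run day block 0.

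Across all probe sets the differences of the 2 drugs from the controls were hardly related, which is across genes and not across independent samples. The Pearson correlation was 0.105 and Spearman's rho 0.066, whereas 100 simulations of unchanged groups that share their controls gave 0.501 on average. The same sign was shared by 51.2% of probe sets against 66.8% in the simulations, and the covariance was 0.0616 against 0.173. Among probe sets at an unadjusted p under 0.01 in both, 4 were lower with both drugs and 0 were higher, where these simulations gave 4.70 (0 to 11) and 4.54 (0 to 9) on average. The correlation in the simulations (0.501) lay far above that of the data (0.105). They therefore cannot say whether these counts differ from those of unchanged groups. The correlation was 0.541 without control 1, 0.349 without control 2 and -0.11 without ACEI 1, and 0.251 with the run day as a block. With a different control array for each drug it was -0.086 or -0.458. The ACEI minus control differences of the 2 run days had a correlation of -0.125.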

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

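The weighing tests in this part were chosen after the result was seen, except the one of raised background on the ARB arrays. 5 gene lists differed between the 2 drugs by the test of the difference itself, all lower with ARB. The mean ARB minus ACEI difference was -1.03 for oligodendrocyte markers, -0.73 for endothelial markers, -0.51 for microglia and macrophage markers, -0.49 for astrocyte markers and -0.29 for ribosomal proteins, and none of the 5 held with an estimated correlation (lowest adjusted p 0.489). The endothelial mean was -0.39 with the run day as a block, where its call was lost, and without ARB 1 only the oligodendrocyte call held (mean -1.07). The ribosomal and astrocyte calls were lost after quantile normalization (means -0.13 and -0.57), and after cyclic loess only the oligodendrocyte call held (-1.01), with a ribosomal mean of -0.089. A signal above the controls also appeared on both ARB arrays in probe sets kept out of the gene tests. The ARB mean was 5.67 times the control mean for the 5S ribosomal RNA probe set, 2.83 times for the median of the 9 added bioB, bioC, bioD and cre controls and 4.45 times for the median of 23 control probe sets for Bacillus, mouse and yeast transcripts. For the opposite-strand probe sets of Gapdh it was 5.62 times at the 3' end, 6.99 times at the 5' end and 10.4 times in the middle, whereas for those of Actb it was between 0.69 and 0.72 times. The size of these ratios rests on which control is taken. 5S ribosomal RNA was at 106 on control 1, 1880 on control 2, and 5813 and 5451 on the ARB arrays. Against control 1 and control 2 alone the ratios were 5.01 and 1.97 for the added controls, 4.83 and 4.12 for the Bacillus, mouse and yeast controls, 9.72 and 3.95, 4.64 and 14.2, and 19.1 and 7.11 for the 3' end, 5' end and middle of Gapdh. For Actb they were 0.42 to 0.58 against control 1 and 0.87 to 2.53 against control 2.

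The 2 ARB arrays stood apart from the other 4 arrays. Run day as the whole cause is argued against, because the differences that ACEI 2 showed from ACEI 1 had a correlation of -0.310 across probe sets with those of ARB from control 1. A candidate explanation is array or RNA quality shared with the second control array. ARB minus ACEI and control 2 minus control 1, which share no array, had a correlation of 0.406. Both differences also lean towards the later run day and chip lot, so this correlation does not isolate quality. The Gapdh 3' to 5' ratio was 1.48 and 1.42 on the ARB arrays, against 1.59 on ACEI 2 and 7.31 on control 2. For Actb it was 2.05 and 1.65, against 1.35 and 3.15. Raised background after scaling of dim arrays stays open: of the 1049 brightest probe sets, where background matters least, 24.4% (SE 1.33) were over 2-fold apart between ARB and ACEI against at most 11.7% within a pair, a share above what background alone predicts but not above 2 times the within-pair share by more than its SE. That SE treats probe sets as independent, which they are not. The share between the drugs compares means of 2 arrays, and the share within a pair compares single arrays, which vary more. A difference between the drugs cannot be told apart from these, because both ARB arrays carry the raised signals, whatever the count of calls: limma called 0 probe sets in ARB versus ACEI (1171 at an unadjusted p under 0.05), but 305 in a fit of these 4 arrays alone and 476 with array weights, where the spread of the controls counts less or not at all.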

How the results depend on the processing

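The fit of the later run day alone was chosen after the result was seen; all other settings were planned. Spp1 and Alox15 were below 0 in each contrast against control under each setting run, while the counts depended on the settings, and where no construction is named the cause was not tested. An offset equal to the median gave 3, 3, 4 and 4 calls (RAS blockade, ACEI, ARB, ARB versus ACEI), the replicate block 3, 2, 4 and 1 (the pairing check gave correlations of replicate differences of 0.045, -0.015 and -0.004, so the numbers did not pair the arrays), quantile and cyclic loess normalization each 1 for RAS blockade (Spp1), and array weights 476 and the fit of only the groups compared 305 for ARB versus ACEI, where the spread of the controls counts less or not at all. Called lists were 11 for ARB versus ACEI with no filter, 5 for RAS blockade with the lowest 60% left out, 5 (RAS blockade) and 3 (ARB versus ACEI) under quantile, and 5, 4 (ARB) and 1 under cyclic loess normalization. Camera with estimated correlation called 0 lists in each contrast, directional fry 0, 0, 0 and 1, and mixed fry 4 for RAS blockade and 0 for ACEI. The later run day alone rests on a lone control array and a lone ACEI array, so only its effect sizes are given. For ARB versus control these are the same as those without control 1. The correlation of the drug effects was 0.168 with the lowest 60% left out, 0.251 with run day as a block and 0.392 within the later day. Signs reversed for Agtr1a (-0.11), Pecam1 (-0.19), and with ARB Vcam1 (-0.10) and Vwf (-0.021) under quantile normalization; for Agtr1a (-0.10) and with ARB Vwf (-0.083) under cyclic loess; with ARB for Edn1 (0.50) and Nos3 (0.22) with run day as a block; and within the later day for Agtr1a (-0.21), Apoe (-0.36), the microglia list (0.11) and with ARB Edn1 (1.47), Nos3 (1.00) and Pecam1 (0.85). Leaving out each array in turn, where a lone array is assumed to vary like the other groups, gave 0 to 60, 0 to 261, 0 to 46 and 0 to 305 calls, 5 to 8, 5 to 9, 4 to 10 and 1 to 5 lists, and a correlation of the drug effects of -0.11 to 0.54. Reversed among these were, for RAS blockade, Agt (-0.084 to 0.555), Ace (-0.85 to 1.83), Agtr1a (-0.16 to 0.57), Edn1 (-1.14 to 2.12), Nos3 (-0.96 to 1.65), Pecam1 (-1.98 to 2.33), Vwf (-0.72 to 1.58), Tfrc (-0.53 to 2.76), Abcb1a (-0.24 to 2.08), Slc1a2 (-0.41 to 1.60), Apoe (-0.47 to 1.34), Mbp (-1.16 to 2.94), Cryab (-1.68 to 0.036), Tgfb1 (-0.088 to 3.23), Atp5po (-2.08 to 0.54) and the oxidative phosphorylation list (-0.68 to 0.23). For ACEI they were Ace (-0.88 to 1.80), Agtr1a (-1.39 to 0.084), Edn1 (-0.48 to 2.78), Nos3 (-0.31 to 2.30), Vcam1 (-0.050 to 0.60), Slc2a1 (-0.95 to 0.036), Pecam1 (-0.50 to 3.81), Vwf (-0.84 to 1.46), the ribosomal list (-0.66 to 0.030) and the endothelial list (-0.077 to 1.31). For ARB they were Ace (-0.82 to 1.86), Edn1 (-1.80 to 1.47), Nos3 (-1.62 to 1.00), Pecam1 (-3.46 to 0.85), Vwf (-0.60 to 1.70) and the oxidative phosphorylation list (-0.73 to 0.19). Of the other results, 2357 values of named genes and 291 of called lists kept their direction and side of the threshold, 64 values of named genes came past it, and 140 of called lists kept their direction without passing. No named gene passed the threshold in the main fit. For named genes an unchanged side therefore means only the same sign without a call. With 2 arrays per group and no detection calls, signal over background limits the genes of low intensity.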

Other observations

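The weighing tests in this part were all chosen after the result was seen. Several gene groups that the text has not yet described gave no call for RAS blockade, and their values follow. Vasoactive genes went both ways (17 of 30 higher, mean 0.14, adjusted p = 0.832): the kinin receptor Bdkrb1 was at 1.62 and the natriuretic peptide Nppc at 1.35, while the vasodilator adrenomedullin, Adm, was at -1.14 and Gch1, which makes the cofactor of nitric oxide synthases, at -1.48 (other probe set 0.29). Of 23 oxidative stress genes 14 were lower (mean -0.12, adjusted p = 0.141), with the extracellular superoxide dismutase Sod3 at 1.09, the xanthine dehydrogenase Xdh at -1.08 and the glutathione reductase Gsr at 0.73. Of 27 immediate early genes 15 were lower (mean -0.03, adjusted p = 0.288), with the phosphatase Dusp1 at 1.43 (other probe sets 2.87 and 0.05), the nuclear receptors Nr4a1 and Nr4a3 at -1.23 (other probe set -0.33) and 0.68, and Zfp36, which destabilises cytokine messages, at -0.74 (other probe set -0.11). Of 25 angiogenic genes 14 were higher (mean 0.16, adjusted p = 0.894), with Pdgfb at 1.68 (other probe set -0.17), Igf1r at -1.43 (0.20), Fgfr2 at 1.19 and Vegfb at 1.07. From the first to the later run day ACEI minus control changed sign for Dusp1 (-0.76 and 3.30) and Igf1r (-0.90 and 1.02). The same held for Nr4a3 (-0.35 and 0.75) and Gsr (-0.01 and 1.35).

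Barrier transporters and junctions had a mean of 0.16 with 9 of 15 higher, although camera gave the direction as down (adjusted p = 0.903), and the lactate transporter Slc16a1 was at 1.20. Glycolysis genes had a mean of 0.06 with the test direction down as well (adjusted p = 0.822), and Pfkfb1 was at 1.44 and Eno1 at -0.77 (other probe set -0.37). Of 12 astrocyte markers 7 were higher (mean 0.09, adjusted p = 0.940), with Aldh1l1 at 0.64 and Apoe at 0.44 (other probe set 1.91), and of 11 oligodendrocyte markers 7 were lower (mean -0.09, adjusted p = 0.374), with Mbp at 0.89 (-1.16 without control 2) and Cryab at -0.82 (other probe set 0.04). Choroid plexus and ependyma markers had a mean of 0.29 (7 of 11 higher, adjusted p = 0.447), with klotho, Kl, at 1.20, ceruloplasmin, Cp, at -1.09 and the cilia regulator Foxj1 at 1.06. Heat shock genes had a mean of -0.00 and a median of -0.22 (adjusted p = 0.387), with the chaperone Hspb2 at 1.46 and Pdia3 at 1.21 (other probe set 0.29). Cell cycle genes had a mean of 0.15 (11 of 19 higher, adjusted p = 0.775), with Pcna at -1.43 (other probe set -0.69), Cdc20 at 1.40 and Cdkn1c at 1.20. From the first to the later run day ACEI minus control changed sign for Pfkfb1 (2.19 and -0.15) and Apoe (0.36 and -1.03). The same held for Cryab (0.07 and -1.45) and Hspb2 (-0.15 and 1.57). In the rank product, a description without a test, the probe sets of Alox15 took the first and the third place for RAS blockade and Spp1 the second.

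Spp1, Alox15 and the other named genes were lower on all 4 treated arrays. Poor RNA on the second control array stays open: between control 1 and ACEI 1, both of the first run day and with low 3' to 5' ratios, the median of the 10 named lower genes was -1.82, but these genes were chosen for lying lower on each treated array than on both controls, which fixes the sign of that value. Fewer macrophages and blood cells in the treated preparations may account for part. The median over the 28 markers tested was -0.34 (SD 0.896, 20 lower), against a median of -2.11 of the named genes. That gap cannot decide, because the named genes were chosen for the size of their falls and the markers were not. In addition, 4 of the 10 named genes are in those lists. Among abundant genes of such cells, Lyz2 was at -1.06, C1qb at -1.30, Alas2 at -2.12, Hbb-b1 at -1.29 and Hbb, chosen after its value was seen, at -0.17. Cd74 and Aif1, chosen in the same way, hardly differed. With ACEI, Spp1 and Alox15 were at -3.97 and -3.67. The ACEI means were -0.12 for the microglia and macrophage list and -0.73 for the blood cell list. An effect of the drugs on inflammatory genes stays open as well. The inflammation list had an adjusted p = 0.464 in camera with an estimated correlation. That test recovered 0% of simulated shifts of -0.5 in this list, so it cannot decide. These explanations cannot be told apart in RNA of whole capillary preparations.

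The 2 control arrays differed from each other. Run day as the whole cause is argued against, because control 2 minus control 1 and ACEI 2 minus ACEI 1, which span the same days, had a correlation of 0.0453 across probe sets. A smaller part played by run day or chip lot is not excluded. Degraded RNA on the second control array is a candidate explanation, since the 2 ratios of 3' to 5' probe sets that lay above background (Gapdh 7.31, Actb 3.15) were both highest on control 2; the 5' probe set of hexokinase was at background there (23.6 against 23.3) and was left out. By list mean, control 2 minus control 1 was -1.39 for endothelial, -0.73 for microglia and macrophage, -0.37 for oligodendrocyte and -0.13 for choroid plexus markers. For pericyte markers it was -0.02, and for blood cell, astrocyte and neuronal markers 0.38, 0.33 and 0.28. Whether the preparations differed in their cells was not tested, and both arrays carry the same group label.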
